A study of Mus musculus with 4 samples.

How the data were processed

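The 4 libraries were poly(A) RNA of N2A cells, a mouse neuroblastoma line, sequenced strand-specifically as 100-base paired reads. Cells received a control shRNA, an shRNA against Ptbp1, an shRNA against Ptbp2, or both, by lipid transfection for 5 hours, and were grown for 3 days. Each group held 1 library, so no spread between replicates could be measured and no test across samples was run. Per the submitters' processing notes, reads were processed with CASAVA, aligned with TopHat to mm9 and assembled with Cufflinks. No versions are given in the sources used here.

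The deposited gene and transcript levels are FPKM with 95% intervals. The transcripts had been assembled in each library with RefSeq transcripts as a guide, and loci that gained a new transcript carry identifiers numbered separately in each library. Per the file headers, a coverage column gives the signal of each transcript as mean read depth per base. The deposited transcript files also carry a score from Cufflinks, which was not used beyond the coordinates beside it. The comparison of libraries was designed for FPKM on the usual scale (per M fragments) and on genes common to all libraries. The unit was different: the deposited FPKM matched a normalizing mass of 5.1 fragments in control, 4.67 in each single knockdown and 4.0 in the double knockdown. The values were therefore divided by the sum of FPKM times length of their own library. A second set of deposited tables, from SpliceTrap, lists 228333 splicing events per library on a fixed list of exon trios. Of these, 218362 were cassette exons. Per the file headers, each event has an inclusion ratio, which is a fraction of transcripts that hold the middle exon, and counts of reads across its 3 junctions. The same deposited tables give exon coverage, a signal equal to reads times 100 over the exon size.

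Genes were named by structure, since the annotation used (GENCODE vM21) is on a later genome build than the data. A trio was named when its chromosome, strand, both intron lengths and middle exon length together occurred in 1 gene symbol. This named 95.0% of cassette trios, against 3 matches when the same trios were looked up on another chromosome. Trios joined by splice sites shared their symbol when 90% of the named ones had it. Of 19768 assembled transcripts that also carried a deposited gene symbol found in the annotation, 99.5% received the same symbol by structure. Genes with fewer than 2 introns stayed unnamed. All coordinates are 1-based on mm9.

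The following choices were made before the data were examined. A gene was counted as higher or lower when log2(FPKM + 1) differed from control by at least 1, FPKM was at least 3 in 1 of both libraries, the Cufflinks status was OK in both, and the intervals did not overlap. An exon was counted when the SpliceTrap ratio differed by at least 0.2 with at least 20 reads over the trio in both libraries. Named genes were the 12 with the largest difference in each direction among counted genes with FPKM of at least 5, without predicted genes. Named exons were the 10 with the largest difference in each direction, and a fixed list of genes with exons known to respond to PTB proteins was looked up. Gene lists were fixed for the PTB family, splicing factors, neuronal functions, REST and miR-124 targets, the cytoskeleton, stress and metabolic pathways, the cell cycle, and other cell types. A list with at least 5 members of FPKM 1 or more was placed by its median among 10000 random lists matched on abundance in 10 bins. These percentiles describe these libraries alone. Lists that hold Ptbp1 or Ptbp2 were also computed without them.

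A second measure was added after the data had been seen, because transcripts assembled separately can gain or lose FPKM between libraries. For genes it was the reads on the fixed exon list, scaled by median of ratios and compared as log2(CPM + 0.1), where CPM is reads per M reads. For exons it was junction inclusion, the mean of both inclusion junctions over that mean plus the skipping junction, with at least 20 such reads in each library. Its 95% intervals are Wilson intervals from the rounded reads. Genes and exons named from the counted ones of a comparison pass the threshold in both measures, 2-fold for genes and 0.2 (20 percentage points) for exons. Within the limits above, genes are ranked by FPKM. Exons are ranked by whichever of their differences, in ratio or in junction inclusion, is smaller. Members of gene lists, the PTB family, Mbnl1 with its exon, and values given for a gene or exon in a further library need not pass it. Some genes and exons that meet these rules are not described here. Of the genes named by the first rule, exon reads held 1 of 12 among the lower genes of the Ptbp2 knockdown and 0 of 12 in each other direction. Of the exons named by the first rule, junction reads held 0 of 10 in each direction. Fold values for genes are on the FPKM + 1 scale unless exon reads are stated. Examples from gene lists were to be the 4 members with the largest difference; members named outside that (such as Actn4, Flnc, Ctsd, Sqstm1, and Rpl8), the double-knockdown exons of Sympk, Agap2 and Nckap1, and Mbnl1 were chosen after their values were seen. Intervals of FPKM, of junction inclusion and of shares of genes cover counting error only. Intervals of a kept share, and of a median difference over exons, come from resampling the exons or genes. They cover the spread between those exons or genes in these libraries, and not that between replicates.

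The Ptbp1 effect was also read in a pair of comparisons that share no library, the Ptbp1 knockdown against control and the double against the Ptbp2 knockdown, and the Ptbp2 effect likewise. By number, the sample records of control and the Ptbp1 knockdown are neighbours, and those of the Ptbp2 and double knockdowns are neighbours elsewhere. Whether the libraries were also made apart is not known here. The Ptbp2 and double knockdowns against control cross this record split. Comparisons for the Ptbp1 effect stay within it, and both for the Ptbp2 effect cross it in the same direction. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used. On simulated data with counting noise alone, the gene rule was run on 8846 genes at the depth of the Ptbp1 knockdown with 200 changed genes. It found 0 of 50 genes changed 1.5-fold, 45 of 50 changed 2.5-fold, 50 of 50 changed 4-fold and 50 of 50 changed 8-fold, with 0 of 8646 unchanged genes counted. On 123163 simulated exons of the same comparison, the exon rule on junction reads found 63 of 67 changed by 0.3, 67 of 67 changed by 0.5 and 0 of 66 changed by 0.1, with 48 of 122963 unchanged exons counted. Of 200 simulated random lists of 20 genes, 14 lay outside the middle 95% in the Ptbp1 knockdown, 6 in the Ptbp2 knockdown and 7 in the double knockdown. Other pseudocounts, filters, scalings, thresholds and measures were tried, and their effect is given in the closing section.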

Results

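Poly(A) RNA of N2A mouse neuroblastoma cells was profiled in 4 libraries, 1 each of cells with a control shRNA, a Ptbp1 knockdown, a Ptbp2 knockdown and a knockdown of both, called the double knockdown below. Ptbp1 and Ptbp2 encode polypyrimidine tract-binding proteins, splicing regulators of which Ptbp1 is made in most cells and Ptbp2 mainly in neurons. Reads summed over the fixed exon list came to 258.26 M in control, 207.23 M in the Ptbp1 knockdown, 242.39 M in the Ptbp2 knockdown and 257.64 M in the double knockdown. A read on overlapping exons counts more than once in these sums, so they are not numbers of sequenced reads. Junction reads numbered 73.78 M, 57.77 M, 69.21 M and 72.23 M in the same order. Mitochondrial transcripts held 9.78% to 10.63% of assembled bases. No difference below could be held against replicates.

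Ptbp1 stood at 149 FPKM (95% interval 145 to 154) in control, 55.4 (54.2 to 56.7) in the Ptbp1 knockdown and 36.8 (34.6 to 38.9) in the double knockdown, which is 37.1% and 24.6% of control. In the Ptbp2 knockdown it stood at 177 FPKM (172 to 182). Ptbp2 stood at 35.2 FPKM (32.9 to 37.5) in control and 10.8 (10.1 to 11.6) in the Ptbp2 knockdown, 30.8% of control. It was 2.16-fold of control in the Ptbp1 knockdown, at 76.0 FPKM (73.0 to 79.1). The double knockdown kept 20.6 FPKM of Ptbp2 (19.2 to 22.0), 58.4% of control, or 43.4% by exon reads. Ptbp3, another family member, was at 29.0 FPKM in control and at 17.8, 19.3 and 16.5 FPKM in the Ptbp1, Ptbp2 and double knockdowns.

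**Figure D1:**
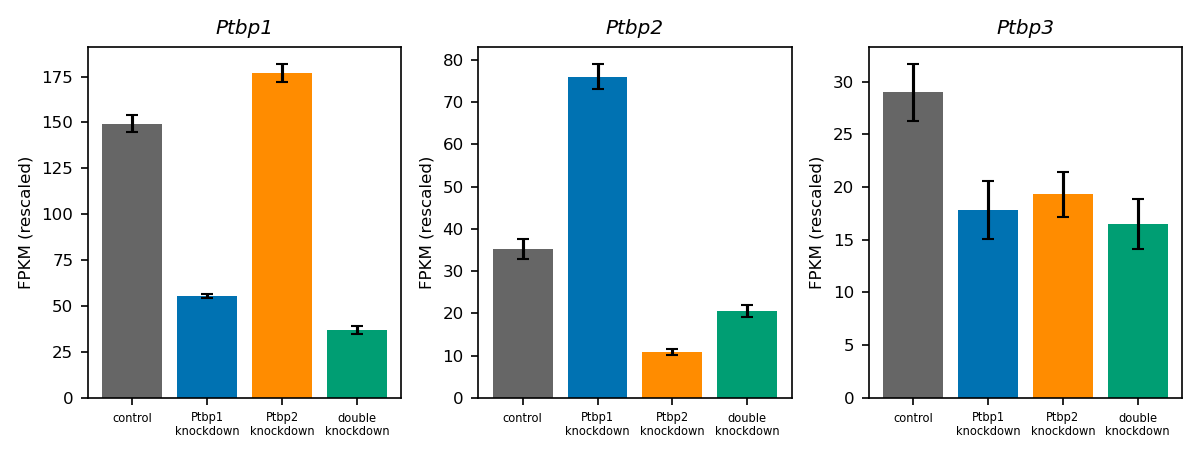
FPKM of Ptbp1, Ptbp2 and Ptbp3 in each of the 4 libraries, with bars from 0 and 95% Cufflinks intervals. Ptbp2 is highest in the Ptbp1 knockdown, at 76.0 FPKM.

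Exons of the family itself differed between the libraries. A 34-nucleotide coding exon of Ptbp2 (mm9 chromosome 3, 119427530 to 119427563), whose skipping shifts the reading frame, was included in 72.2% of junction reads in control (67.0 to 76.9), 94.5% in the Ptbp1 knockdown (92.3 to 96.1), 42.7% in the Ptbp2 knockdown (32.9 to 53.1) and 84.5% in the double knockdown (77.9 to 89.5). The matching 34-nucleotide exon of Ptbp3 (chromosome 4, 59559021 to 59559054) was at 28.0%, 57.5%, 30.6% and 77.4%.

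The comparison of the Ptbp1 knockdown with control asks which genes and exons depend on Ptbp1 while Ptbp2 is present. Genes of neurons were among the higher ones, and genes of the actin cytoskeleton among the lower ones. Dbh, which makes noradrenaline from dopamine, was 3.85-fold higher (16.3 to 65.3 FPKM), and Mcam, a cell adhesion molecule, was also 3.85-fold higher (9.45 to 39.3 FPKM). Vamp2, the synaptic vesicle SNARE protein, went from 28.4 to 71.8 FPKM, or 2.48-fold. Flna, which crosslinks actin filaments, was 3.11-fold lower. The scaffold protein Iqgap1 was 2.29-fold lower, and cytoplasmic actin Actg1 was 3.48-fold lower by FPKM and 2.10-fold lower by exon reads.

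By the planned FPKM rule, 186 of 9270 genes were higher and 115 lower, and 62 and 11 of them passed 2-fold in exon reads as well. The largest of the 62 further included the G protein subunits Gnb3 (3.33-fold) and Gng4 (2.59-fold), the kinase Map3k13 (2.65-fold), Necab3 (3.24-fold), Strip2 (3.23-fold), Ppp1r12b (3.09-fold), Ebf4 (2.90-fold), Angpt4 (2.64-fold) and Rnf112 (2.47-fold). The 11 lower genes included Ptbp1 itself and, besides those above, the actin-binding Cald1 (2.96-fold), Cnn2 (2.13-fold) and Tmod3 (2.02-fold), together with Ndufa12 (3.34-fold), Atp6v0e (2.80-fold) and Anxa2 (2.00-fold). Higher genes made up 61.8% of those counted by FPKM and 88.0% by exon reads alone (132 higher, 18 lower), but the balance by FPKM turned with a single divisor for all libraries (125 higher, 167 lower), a pseudocount of 5 (60 and 68) and FPKM of at least 10 (84 and 88). Of the 301 genes counted by FPKM, 67 had the opposite sign in exon reads.

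Among the fixed lists, actin cytoskeleton genes had a median log2 difference of -0.54 (percentile 0.0 among matched random lists) and -0.75 by exon reads. Beside Flna, Vim went from 500 to 307 FPKM and Actn4 from 53.7 to 32.0, while Flnc, at 7.91 and 7.83 FPKM, were close in both. Synaptic and axonal genes had a median of 0.23 (percentile 100.0), with 22 of 34 measured members above control, among them Gabbr1 (9.48 to 21.0 FPKM), Sv2a (8.65 to 16.9), Grin1 (6.82 to 13.0) and Nlgn2 (5.34 to 10.2). Targets of the neuronal gene repressor REST had a median of 0.38 (percentile 99.9) with 13 of 14 above control, for example Celsr3 (7.05 to 11.1 FPKM) and Rundc3a (45.2 to 65.1). The repressor complex itself had a median of 0.01 (percentile 40.0). Targets of miR-124, a neuronal microRNA, had a median of -0.36 (percentile 0.2), with 1 of 11 above control. This list holds Ptbp1 itself; without it the median was -0.31 (percentile 0.5). Neuronal splicing regulators had a median of 0.26 (percentile 97.5), with Celf5 from 2.21 to 4.93 FPKM and Celf6 from 5.38 to 9.08. Lysosomal genes had a median of 0.16 (percentile 98.4), with Ctsd from 133 to 151 FPKM and Sqstm1 from 154 to 175. These 6 of 20 lists lay outside the middle 95% in both measures, which come from the same libraries. Lists of randomly drawn genes would give 1 in a single measure. Members of a fixed list can vary together, so more than that may lie outside without an effect of the knockdown. By FPKM 9 lay outside, with ribosomal protein genes at a median of -0.33 (percentile 0.1, by exon reads 3.6), cholesterol synthesis genes at -0.28 (0.7, by exon reads 4.4) and the PTB family, which holds Ptbp1, at -0.42 (1.0, by exon reads 7.7).

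Several exons went from nearly skipped to mostly included in the Ptbp1 knockdown. The 21-nucleotide coding exon of Exoc1, a vesicle tethering protein (chromosome 5, 76969772 to 76969792), went from 5.03% to 59.5%. A 42-nucleotide coding exon of the chromatin protein Dpf2 (chromosome 19, 5903731 to 5903772) went from 10.1% to 65.5%, and the 107-nucleotide exon of ceramide synthase Cers5, coding or untranslated by transcript (chromosome 15, 99567978 to 99568084) from 3.74% to 62.3%. In the opposite direction, a 99-nucleotide coding exon of Flnc (chromosome 6, 29402799 to 29402897) went from 86.6% (78.4 to 92.0) to 30.4% (22.4 to 39.1), and a 93-nucleotide coding exon of the microtubule protein Map2 (chromosome 1, 66478101 to 66478193) from 60.9% to 21.6%.

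By SpliceTrap ratio, 775 of 138816 cassette events were higher and 561 lower, of which 54.3% had too few junction reads to be checked. In both measures 256 events (222 exons) were higher and 107 (96 exons) lower. The higher ones included Slc8a1 (9.38% to 72.4%), Plekha6 (15.8% to 74.3%), Fbxo25 (17.8% to 74.5%), Anxa7 (3.52% to 57.3%), Epb41l2 (38.8% to 91.9%, a 168-nucleotide exon) and Tnrc6a (27.2% to 82.1%). The lower ones included Atp2b4 (80.4% to 21.4%), Arhgap39 (80.1% to 33.0%), Synrg (61.5% to 18.0%), Ehhadh (92.3% to 51.3%), Dmxl2 (97.3% to 52.4%), Myo5a (68.9% to 30.8%), Meg3 (55.0% to 14.3%) and Cep152 (79.9% to 40.7%). Other event types counted by ratio were 14 higher and 13 lower retained introns, 32 and 27 alternative 5' splice sites, and 65 and 42 alternative 3' splice sites.

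Genes on the fixed list of known PTB exons were often among them. Of 56 measured genes, 20 (35.7%) had an exon changed in both measures in the Ptbp1 knockdown, against 2.85% of all 9985 genes measured. In the Ptbp2 knockdown this held for 6 (10.7% against 1.28%) and in the double knockdown for 24 (42.9% against 4.55%). Any cassette exon of a listed gene counted, not only the exon known to respond. The genes set against the list were not matched on number of exons or on junction reads. The neuron-specific 36-nucleotide exon of clathrin light chain Clta (chromosome 4, 44044272 to 44044307) went from 27.7% to 67.0% in the Ptbp1 knockdown, and a 27-nucleotide exon of the scaffold protein Ank3 (chromosome 10, 69443572 to 69443598) from 5.02% to 46.6%.

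The comparison of the Ptbp2 knockdown with control asks what Ptbp2 does while Ptbp1 is present. Fewer genes were higher than lower. Socs2, a suppressor of cytokine signalling, was 3.23-fold higher (14.7 to 49.9 FPKM), the differentiation inhibitor Id4 was 2.63-fold higher (10.2 to 28.3) and Ddc, which makes dopamine, was 2.49-fold higher (5.26 to 14.6). The neurotrophin receptor Ngfr was 3.03-fold lower (66.8 to 21.4 FPKM), the nicotinic receptor Chrna7 2.60-fold lower (24.3 to 8.74) and the synaptic protein Cplx2 2.69-fold lower (6.72 to 1.87). Dbh was 2.42-fold lower, at 6.12 FPKM against 16.3.

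By FPKM, 132 of 9041 genes were higher and 203 lower, and 13 and 75 passed in exon reads too. Further higher genes were Ankrd45 (2.47-fold), Lix1 (2.39-fold), Rsph1 (2.38-fold), Radil (2.25-fold), Map1lc3a (2.18-fold), Arid3a (2.16-fold), the clock gene Arntl (2.13-fold), Tusc2 (2.09-fold) and Cfap74 (2.04-fold). Further lower genes were Sptbn1 (4.97-fold by FPKM, 2.97-fold by exon reads), Lypla1 (3.55-fold), Gdap1 (2.82-fold), Casc4 (2.52-fold), Pi16 (2.46-fold) and Ltbp3 (2.43-fold). The mitochondrial pyruvate carrier Mpc1 was listed at 0 in the Ptbp2 knockdown, and was 3.03-fold lower by exon reads. Higher genes made up 39.4% of those counted by FPKM and 15.4% by exon reads alone (25 higher, 137 lower). Of the 335 counted, 68 had the opposite sign in exon reads.

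Synaptic and axonal genes lay on the other side from the Ptbp1 knockdown, with a median of -0.37 (percentile 0.0) and 4 of 34 above control. Grin1 stood at 3.52 FPKM against 6.82, L1cam at 27.5 against 49.4 and Syt1 at 23.2 against 39.8. Genes of cholesterol synthesis had a median of -0.34 (percentile 0.1), among them Cyp51 (71.9 to 32.0 FPKM) and Nsdhl (26.2 to 14.3). Glycolysis genes had a median of -0.20 (percentile 0.7), with Pfkp from 97.5 to 63.3 FPKM and Aldoc from 9.87 to 5.09. Ribosomal protein genes had a median of 0.18 (percentile 99.4), with Rpl8 from 1660 to 2110 FPKM. These 4 of 20 lists were outside in both measures, and 7 by exon reads. Actin cytoskeleton genes had a median of 0.13 (percentile 91.2).

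Exons that were mostly included in control were skipped in the Ptbp2 knockdown. The 130-nucleotide exon of the laminin receptor Itga6, which holds coding and untranslated bases (chromosome 2, 71691591 to 71691720) went from 86.2% (83.6 to 88.4) to 28.7% (25.3 to 32.5), and the 63-nucleotide coding exon of the membrane skeleton protein Epb41l2 (chromosome 10, 25213373 to 25213435) from 89.6% to 22.3%. The 42-nucleotide coding exon of the spindle protein Numa1 (chromosome 7, 109150809 to 109150850) went from 84.4% to 32.1% and the 84-nucleotide coding exon of the transcription factor Lef1 (chromosome 3, 130893941 to 130894024) from 82.0% to 26.3%. The 54-nucleotide coding exon of the splicing regulator Mbnl2 (chromosome 14, 120794934 to 120794987) went the other way, from 48.1% (37.6 to 58.9) to 76.5% (65.6 to 84.5).

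By ratio, 456 of 137655 events were higher and 579 lower, with 65.5% under the junction minimum. In both measures 35 events (30 exons) were higher and 118 (104 exons) lower. The higher ones included Sh3glb1 (14.6% to 60.5%), Golgb1 (53.8% to 87.8%), Dctn4 (30.6% to 60.7%), Slain1 (31.9% to 60.9%), Adam15 (23.5% to 51.2%), Numb (55.0% to 96.7%), Cadm1 (32.1% to 56.9%), Trerf1 (57.7% to 82.5%) and Myt1 (56.5% to 82.6%). The lower ones included Limch1 (69.4% to 15.9%), Slmap (83.3% to 29.2%), Arhgef12 (81.3% to 26.8%), Dst (93.7% to 34.9%), Mdm1 (64.0% to 20.6%) and Tbc1d24 (74.1% to 31.2%). Retained introns counted by ratio were 20 higher and 14 lower, alternative 5' splice sites 27 and 27, and alternative 3' splice sites 53 and 54.

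On the fixed list, 3 neuronal exons that were higher in the Ptbp1 knockdown were lower in the Ptbp2 knockdown. The 110-nucleotide coding exon of the postsynaptic scaffold Dlg4 (chromosome 11, 69857160 to 69857269) stood at 47.3% in control (42.2 to 52.4), 70.9% in the Ptbp1 knockdown (66.3 to 75.1), 26.3% in the Ptbp2 knockdown (22.0 to 31.0) and 86.0% in the double knockdown (82.5 to 88.8). The 151-nucleotide coding exon of the GABA-B receptor gene Gabbr1 (chromosome 17, 37204159 to 37204309) was at 62.8%, 93.6%, 27.5% and 96.4%, and the 93-nucleotide coding exon of Exoc7 (chromosome 11, 116158885 to 116158977) at 55.1%, 83.5%, 29.4% and 90.1%.

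**Figure D2:**
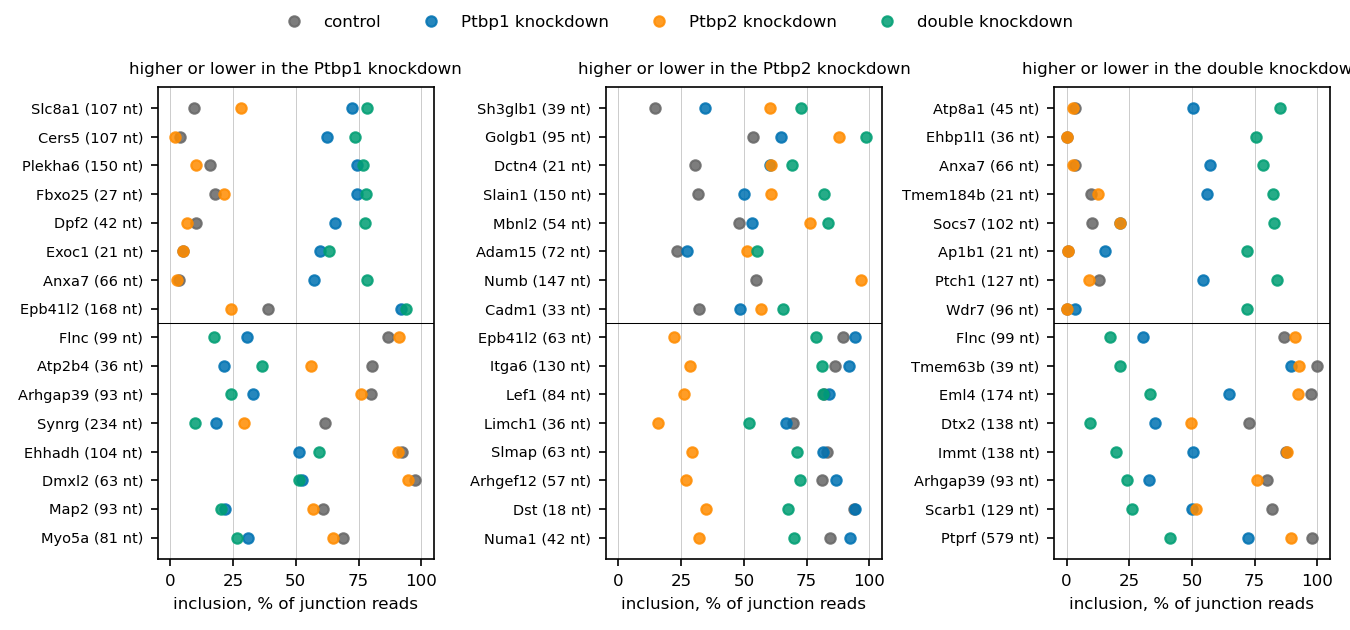
Inclusion of cassette exons as % of junction reads in the 4 libraries, up to 8 exons higher (top) and 8 lower (bottom) in each knockdown, for libraries with at least 20 junction reads. Itga6 and Epb41l2 are low in the Ptbp2 knockdown alone, at 28.7% and 22.3%.

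The comparison of the double knockdown with control asks what changes when both proteins are reduced. Flna was 3.62-fold lower and Cald1 3.90-fold lower, with Cald1 at 2.06-fold by exon reads. Vamp2 was 2.60-fold higher (75.4 FPKM), Socs2 2.70-fold higher (41.6 FPKM) and Mcam 2.80-fold higher (28.3 FPKM). Ngfr was 2.96-fold lower (21.9 FPKM). Dbh, at 18.2 FPKM, was close to its control level of 16.3.

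By FPKM, 174 of 9164 genes were higher and 140 lower, and 35 and 46 passed in both measures. Other higher genes were Tmem230 (3.75-fold), Catsper2 (3.61-fold), Ankrd45 (3.56-fold), Fbxo48 (3.46-fold), Hoxc6 (3.33-fold), Fam120c (2.80-fold) and Tusc2 (2.64-fold). Map6d1 was listed at 0 in control, and was 2.18-fold higher by exon reads. Lower genes were Ptbp1 (3.98-fold), the ETS factor Elk3 (3.00-fold), the thymidylate synthase gene Tyms (2.94-fold), Lypla1 (2.72-fold), Pmp22 (2.69-fold), Aldh7a1 (2.61-fold), Emp1 (2.60-fold) and Stmn2 (2.59-fold). Higher genes made up 55.4% of those counted by FPKM and 37.1% by exon reads alone (62 higher, 105 lower); with a single divisor for all libraries, 603 would be higher and 74 lower. The balance by FPKM turned under other scalings, with 142 higher and 173 lower after median centring and 146 and 172 after upper-quartile scaling. Of the 314 counted, 62 had the opposite sign in exon reads.

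Cholesterol synthesis genes had the lowest list median next to the PTB family, at -0.50 (percentile 0.0) with 1 of 16 above control. Lss stood at 23.6 FPKM against 56.6 in control, Cyp51 at 29.5 against 71.9 and Nsdhl at 11.4 against 26.2. The PTB family and cofactors had a median of -0.68 (percentile 0.0), which is partly set by the shRNA targets on this list; the 4 other members had a median of -0.42, too few for a percentile. Medians were lower than in most random lists also for glycolysis genes -0.21 (percentile 0.6) and actin cytoskeleton genes -0.17 (percentile 1.4). Synaptic and axonal genes had a median of 0.02 by FPKM and -0.14 by exon reads (percentiles 36.3 and 2.5), and 4 of 20 lists, the PTB family among them, were outside in both measures.

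**Figure D3:**
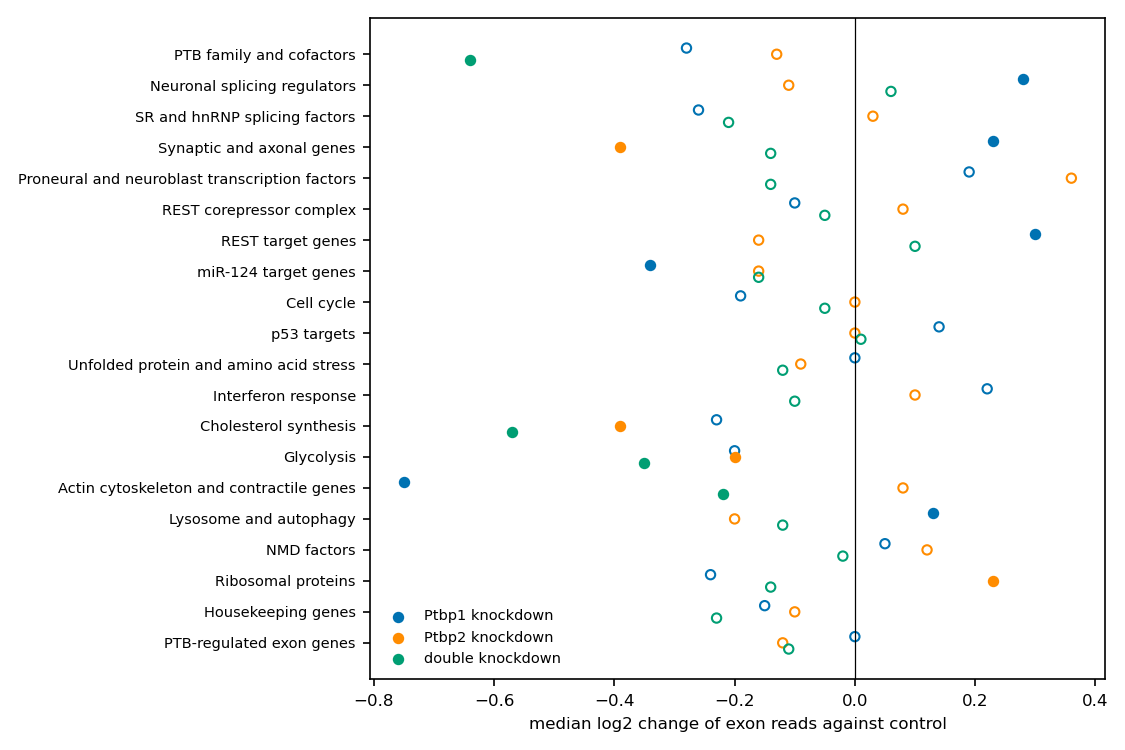
Median log2 difference of exon reads from control for each fixed gene list with at least 3 measured members, in the 3 knockdowns; filled points lie outside the middle 95% of matched random lists in both measures. The actin cytoskeleton list is lowest in the Ptbp1 knockdown, at -0.75.

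The double knockdown had the most changed exons. A 21-nucleotide coding exon of the clathrin adaptor gene Ap1b1 (chromosome 11, 4933245 to 4933265) was at 0.401% in control (0.0881 to 1.16), 15.4% in the Ptbp1 knockdown, 0.399% in the Ptbp2 knockdown and 71.8% in the double knockdown (67.5 to 75.7). The 45-nucleotide coding exon of the phospholipid flippase Atp8a1 (chromosome 5, 68147889 to 68147933) was at 3.34%, 50.4%, 2.63% and 85.1%. A 138-nucleotide coding exon of the mitochondrial protein Immt (chromosome 6, 71802724 to 71802861) was at 87.6%, 50.3%, 87.8% and 19.8%, and the 39-nucleotide coding exon of Tmem63b (chromosome 17, 45815912 to 45815950) at 100%, 89.5%, 92.6% and 21.5%.

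By ratio, 866 of 138557 events were higher and 842 lower, with 47.4% under the junction minimum, and 373 (318 exons) and 243 (215 exons) passed both measures. Other higher exons were in Ehbp1l1 (0 to 75.4%; 30 junction reads in control allow up to 11.4%), Anxa7 (3.52% to 78.5%), Tmem184b (9.94% to 82.4%), Socs7 (10.1% to 82.8%), Ptch1 (13.0% to 84.0%), Ralgapa1 (6.82% to 76.1%) and Dock10 (3.57% to 72.7%). Other lower exons were in Flnc (86.6% to 17.5%), Eml4 (97.3% to 33.3%), Dtx2 (72.8% to 9.47%), Arhgap39 (80.1% to 24.2%), Scarb1 (81.8% to 26.0%), Ptprf (97.8% to 41.3%), Pdzd4 (93.3% to 39.7%) and Cspp1 (92.4% to 39.7%). Retained introns counted by ratio were 19 higher and 20 lower, alternative 5' splice sites 43 and 29, and alternative 3' splice sites 83 and 48.

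Some exons differed from control by at least 0.2 in the double knockdown and by under 0.1 in each single knockdown. By ratio these were 98 of 832 higher and 211 of 799 lower events, of which 27 and 37 held in junction reads. The 96-nucleotide coding exon of Wdr7 (chromosome 18, 63951450 to 63951545) was at 0% in control (up to 6.64), 3.45% and 0% in the single knockdowns and 71.8% in the double knockdown (56.4 to 82.8). The 126-nucleotide untranslated exon of the polyadenylation factor Sympk (chromosome 7, 19613246 to 19613371) went from 0.415% to 66.2%, with 1.80% and 0.285% in the singles, and the 60-nucleotide coding exon of Agap2 (chromosome 10, 126527198 to 126527257) from 1.92% to 46.0%. The 18-nucleotide coding exon of Nckap1 (chromosome 2, 80411370 to 80411387) went from 65.5% to 27.6%, with 64.9% and 62.5% in the singles. Conversely, 577 events changed in a single knockdown and by under 0.1 in the double, 49 of them in both measures. The exon of Itga6, at 81.3% in the double knockdown, met this limit, with a ratio difference of -0.06 from control. The 63-nucleotide exon of Epb41l2, at 78.7%, did not, with a ratio difference of -0.21.

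The comparisons that share no library ask whether each protein's effect depends on the other. Across 9366 genes, which are not independent replicates, the Ptbp1 effect without and with Ptbp2 depleted correlated with r = 0.60 by exon reads and 0.24 by FPKM. Of 161 genes at least 2-fold different by exon reads in the Ptbp1 knockdown, 155 (96.3%) had the same sign in the double against the Ptbp2 knockdown. By FPKM it was 214 of 311 (68.8%). For the Ptbp2 effect r was 0.60 by exon reads and 0.26 by FPKM. The same sign was kept by 169 of 178 genes (94.9%) by exon reads and 230 of 348 (66.1%) by FPKM. Both comparisons for the Ptbp2 effect cross the record split in the same direction. A difference between the sides of that split would also give the same sign, and cannot be told apart from Ptbp2 loss. For Ptbp1 as for Ptbp2, both comparisons use the same shRNA. An effect of that shRNA other than through its target would keep the sign too, and cannot be told apart either. For the Ptbp1 effect r was 0.62 by junction reads over 121204 events. By junction reads 280 of 289 higher events (96.9%) stayed higher, with a median of 0.27 in the first comparison and 0.39 with Ptbp2 also depleted. Of its lower events 82.9% stayed lower, with medians of -0.25 and -0.19. By SpliceTrap ratio r was 0.32, and 505 of 751 higher events (67.2%) stayed higher, with medians of 0.31 and 0.17. The median of higher events thus grew by junction reads and shrank by ratio. All events in this paragraph were picked by size in the first comparison alone. Noise by itself would therefore shrink the second median, for either protein and in either direction. Of the lower events 57.5% stayed lower by ratio, with medians of -0.32 and -0.07. Depletion also differed: by exon reads Ptbp1 fell from 621 to 194 CPM in the first comparison and from 714 to 143 in the second. The medians therefore do not isolate the part of Ptbp2. For the Ptbp2 effect r was 0.24 by junction reads and 0.08 by ratio. By junction reads 118 of 163 lower events (72.4%) stayed lower, with a median of -0.25 in the first comparison and -0.09 with Ptbp1 also depleted. By ratio 308 of 557 lower events (55.3%) stayed lower, with medians of -0.3 and -0.02. Of the higher events of the Ptbp2 effect 37 of 45 (82.2%) stayed higher by junction reads, with medians of 0.24 and 0.13. By ratio it was 191 of 442 (43.2%), with medians of 0.32 and 0.0. The same sign was thus kept by 499 of 999 events (49.9%) by ratio.

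Genes with a changed exon were compared with the other genes for a change in level. By ratio and FPKM, 30 of 615 such genes (4.88%, exact interval 3.32 to 6.89) were counted as changed in level in the Ptbp1 knockdown, against 246 of 8583 others (2.87%, 2.52 to 3.24). In the Ptbp2 knockdown it was 16 of 445 (3.60%) against 291 of 8534 (3.41%), and in the double knockdown 24 of 771 (3.11%) against 265 of 8326 (3.18%). With both measures asked for exons and genes, it was 6 of 266 (2.26%, 0.832 to 4.84) against 0.689% of the others (0.528 to 0.885) in the Ptbp1 knockdown. In the Ptbp2 knockdown it was 1 of 116 (0.862%, 0.0218 to 4.71) against 0.922%. In the double knockdown it was 2 of 422 (0.474%, 0.0574 to 1.7) against 0.884%. The genes compared were not matched on abundance, number of exons or junction reads. Gabbr1 had both in the Ptbp1 knockdown, with its exon at 93.6% and its level at 21.0 FPKM against 9.48.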

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

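The tests of this part were chosen only after the data were seen. No group had 4 or more samples, so no sample was tested for lying far from the others of its group. Results are listed here because the effect of 1 shRNA had opposite signs in both measures with and without the other, or because a signal lay in data that the comparisons above did not use.

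The level of Ptbp1 differed in opposite directions between libraries with and without the Ptbp2 shRNA: by exon reads log2 0.20 with Ptbp1 intact and -0.45 with Ptbp1 depleted (0.25 and -0.58 by FPKM). Both libraries of the second pair carry the Ptbp1 shRNA, and a difference in its efficiency between them was not tested. The 18-nucleotide exon of Tbc1d24 was at 74.1% in control and 31.2% in the Ptbp2 knockdown, a difference of -42.9 percentage points, and at 88.9% in the Ptbp1 (74.7 to 95.6) and 97.8% in the double knockdown (88.4 to 99.6), a difference of 8.9 whose intervals overlap. Opposite signs were looked for among the exons with the 10 largest differences in each direction and those of the fixed PTB list that changed in both measures. On that list the Ptbp2 shRNA gave -21.0 points without and 15.1 with the Ptbp1 shRNA for the exon of Dlg4, -35.3 and 2.8 for Gabbr1, and -25.7 and 6.6 for Exoc7. In the second pair the intervals lie apart for Dlg4 (66.3 to 75.1 and 82.5 to 88.8), and overlap for Gabbr1 (90.6 to 95.7 and 93.7 to 98.0) and Exoc7. Of the 98 exons lower in the Ptbp2 knockdown with at least 20 junction reads in each library, 24 had the opposite sign beside the Ptbp1 shRNA by junction reads, and 7 of the 45 with at least 100 had it. With 1 library per group, no difference between the effects was tested.

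Assembled loci of a single exon, which the gene comparisons leave out, numbered 20173 with FPKM above 0 in control, 28046 in the Ptbp1 knockdown, 21731 in the Ptbp2 knockdown and 27140 in the double knockdown (1.39-fold, 1.08-fold and 1.35-fold of control). On the strand of a named gene and inside it lay 5701, 7873, 6412 and 8770 of them, and outside named genes 12535, 17327, 13295 and 16084. On the opposite strand of a named gene lay 1937, 2846, 2024 and 2286. Those outside named genes held 18.4%, 18.4%, 19.9% and 17.9% of assembled bases. Their larger number in the Ptbp1 and double knockdowns thus came without a larger share of the signal. The cause of the larger numbers was not tested.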

How the results depend on the processing

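Among the tests of this part, those on exon reads, junction reads, both measures together, the deposited divisor, SpliceTrap's modality, the uncorrected ratio, the largest locus of each gene and lists without the shRNA targets were chosen only after the data were seen; pseudocounts, filters and thresholds were planned. Of 106 values that answer a comparison under the settings chosen in advance, 74 stayed within the allowed range and 32 moved. Of 76 under added settings 22 stayed and 54 moved. None was labelled as reversed, but a count could only be labelled as staying or moving. The balance of higher and lower genes did turn under some settings, as given in the next paragraph. For the medians of single gene lists, 51 of 51 stayed under settings chosen in advance and 19 of 20 under added ones (the actin list in the Ptbp1 knockdown moved to -0.75 by exon reads), where staying means inside the 95% bootstrap interval over the list's members. That interval is wide: the REST target median in the Ptbp1 knockdown went from 0.38 to 0.20 with FPKM of at least 5, and the glycolysis median in the double knockdown from -0.21 to -0.35 by exon reads. Counts stayed within 1.5 times of the main count under median centring, upper-quartile scaling, no filter on low FPKM, no requirement on the intervals, the largest locus of each gene, the sum of isoform FPKM, 10 or 50 reads over the trio and 1 event per exon. Each group had 1 library, so no library could be left out in turn. No paired analysis was possible because the labels give no pairing of libraries. The record split lies along the Ptbp2 shRNA and could not be separated from it. Each tracked locus counted on its own was not run, since loci are numbered separately in each library; the largest locus of each gene took its place.

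For genes higher and lower in the Ptbp1, Ptbp2 and double knockdowns, the main counts were 186 and 115, 132 and 203, and 174 and 140. A pseudocount of 5 gave 60 and 68, 70 and 84, and 84 and 77, as it shrinks folds by construction; a pseudocount of 0.1 gave 283 higher genes in the Ptbp1 knockdown. FPKM of at least 10, which tests fewer genes, gave 84 higher and 88 lower genes in the Ptbp1 knockdown, 81 higher and 131 lower in the Ptbp2 knockdown and 115 higher in the double knockdown. Asking for 2-fold in both FPKM and exon reads, a stricter rule by construction, gave 62 and 11, 13 and 75, and 35 and 46. FPKM as deposited with 1 divisor gave 603 and 74 in the double knockdown, as that library's deposited values are on a larger scale, and 125 and 167 in the Ptbp1 knockdown. The balance of higher and lower genes thus turned in the Ptbp1 knockdown with the single divisor, a pseudocount of 5 and FPKM of at least 10. In the double knockdown it turned with both measures, with exon reads alone (62 and 105), with median centring (142 and 173) and with upper-quartile scaling (146 and 172).

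Exon reads gave 18 lower genes in the Ptbp1 knockdown, 25 higher in the Ptbp2 knockdown and 62 higher in the double knockdown, and 7 lists in place of 4 outside the middle 95% in the Ptbp2 knockdown. They gave log2 differences of -1.68 (main -1.41) and -2.12 (main -1.99) for Ptbp1 in the Ptbp1 and double knockdowns, and -1.88 (main -1.61) and -1.21 (main -0.75) for Ptbp2 in the Ptbp2 and double knockdowns. The correlations across genes of each protein's effect were 0.60 and 0.60 by exon reads (main 0.24 and 0.26), 0.17 and 0.19 with a pseudocount of 0.1, and 0.21 for Ptbp1 with FPKM of at least 10 on average. The cause was not tested.

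For cassette exons higher and lower in the Ptbp1, Ptbp2 and double knockdowns, the main counts were 775 and 561, 456 and 579, and 866 and 842. A change of at least 0.1 gave 1787 and 1517, 1209 and 1723, and 1758 and 2088, where the balance in the double knockdown turned as with 10 reads over the trio (955 and 993), and one of at least 0.3 gave 407 and 298, 248 and 285, and 532 and 460, by construction. Junction reads alone gave 314 and 146, 49 and 176, and 425 and 305, and both ratio and junction reads 256 and 107, 35 and 118, and 373 and 243. With a SpliceTrap modality given in both libraries the counts were 475 and 257, 183 and 280, and 563 and 473, and with FPKM of at least 3 in both libraries 515 and 237, 224 and 260, and 428 lower in the double knockdown. The ratio before SpliceTrap's correction gave 719 higher in the Ptbp2 knockdown. With a modality given, retained introns numbered 13, 17 and 19 in the 3 knockdowns (main 27, 34 and 39), alternative 5' splice sites 34, 22 and 44 (main 59, 54 and 72), and alternative 3' splice sites 59, 55 and 79 (main 107, 107 and 131).

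By junction reads the correlations across exons were 0.62 for Ptbp1 and 0.24 for Ptbp2 (main 0.32 and 0.08). Exons of the double knockdown beyond both singles numbered 40 higher and 63 lower by junction reads (main 98 and 211), and 29 higher when under 0.05 was asked of each single, and exons of a single knockdown absent from the double numbered 88 (main 577). The share of genes with a changed exon that also changed in level was 2.26%, 0.862% and 0.474% with both measures asked for (main 4.88%, 3.60% and 3.11%). Depth limits the check of exons: 54.3%, 65.5% and 47.4% of exons counted by ratio had too few junction reads to be checked.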

Other observations

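Of the tests in this part, those on exon length and abundance, on well-covered exons and on exons that Ptbp1 represses were set before their result was seen, and the others only after. The remaining fixed lists are given first, by exon reads in the Ptbp1, Ptbp2 and double knockdowns. Medians were -0.26, 0.03 and -0.21 for SR and hnRNP splicing factors, 0.19, 0.36 and -0.14 for proneural transcription factors, -0.19, 0.00 and -0.05 for the cell cycle, and 0.14, 0.00 and 0.01 for p53 targets. They were 0.00, -0.09 and -0.12 for the unfolded protein and amino acid stress response, 0.22, 0.10 and -0.10 for the interferon response, 0.05, 0.12 and -0.02 for factors of nonsense-mediated decay, -0.15, -0.10 and -0.23 for housekeeping genes, and 0.00, -0.12 and -0.11 for the genes with known PTB exons. Outside the middle 95% by exon reads but not by FPKM were, in the Ptbp2 knockdown, proneural factors (percentile 100.0, by FPKM median 0.08 and percentile 70.1), lysosomal genes (-0.20, percentile 0.9, by FPKM -0.09 and 11.3) and genes with known PTB exons (percentile 0.4, by FPKM -0.07 and 4.9). In the double knockdown, genes with known PTB exons (percentile 2.4, by FPKM 0.02 and 26.1) also lay outside by exon reads alone. Synaptic and axonal genes did so there at the limit (-0.14, percentile 2.5, by FPKM 0.02 and 36.3). Histone, immune and epithelial lists had 0 measured members, astrocyte and oligodendrocyte markers 1, and fibroblast and muscle markers 2 each, too few for a percentile.

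Exons lower in the Ptbp2 knockdown differed less beside the Ptbp1 shRNA: among 98 exons, the median difference was -27.3 percentage points in the Ptbp2 knockdown against control and -9.9 in the double against the Ptbp1 knockdown, a kept share of 0.36 (0.24 to 0.41). Intervals in this paragraph come from resampling the exons or genes. Chance in exons picked for being low stays open: 45 exons with at least 100 junction reads in each library kept 0.59 (0.39 to 0.89), so part of the return may come from counting. Lower Mbnl1 mRNA as the only cause is not excluded either, since Mbnl1 itself kept 0.86, above the 0.36 of all 98 exons but inside the interval of those 45. More Ptbp2 was left in the double knockdown, at 57.9 CPM by exon reads against 36.3 in the Ptbp2 knockdown. As a cause, this cannot be told apart from an effect of Ptbp1 loss. The 74 lower genes kept 0.75 (0.68 to 0.82), 0.39 more than the exons. The 13 higher genes kept 0.21, with a wide interval (0.11 to 0.71) that covers the 0.36 of the exons and overlaps that of the lower genes. The fall of Ptbp2 within the comparison was not weaker beside the Ptbp1 shRNA, from 279 to 57.9 CPM, than without it, from 134 to 36.3. Whether Ptbp1 represses these exons is not decided either, with a median difference of -1.4 points (-4.3 to 1.7) in the Ptbp1 knockdown and 47 of 98 higher, but 5.5 points and 28 of 45 higher among those with at least 100 junction reads.

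Actin cytoskeleton genes were lower in both libraries with the Ptbp1 shRNA: among the 16 members with FPKM of at least 3 in a library, 15 in the Ptbp1 knockdown and 13 in the double knockdown by exon reads, with medians of -0.68 and -0.25. Separate assembly of transcripts is argued against, as the exon list is fixed and the full list of 17 measured members, with medians of -0.75 and -0.22, stayed at percentile 1.4 or below by exon reads. Exon length, summed over the fixed exon list, is argued against, as the 16 members stayed at percentile 0.7 or below among lists matched on it and on abundance. Abundance was matched in broad bins only, so it is not excluded. By exon reads in the Ptbp1 knockdown, SR and hnRNP splicing factors had 0 of 22 members above control (median -0.26). Ribosomal protein genes had 2 of 24 (-0.24), while lysosomal genes had 11 of 16 (0.13). An effect of the Ptbp1 shRNA other than through Ptbp1 cannot be told apart from loss of Ptbp1, since a single shRNA was used; the double against the Ptbp2 knockdown gave -0.47. Loss of Ptbp1 is thus an open hypothesis for these genes.

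Mbnl1, which encodes a splicing regulator, stood at 36.4 FPKM in control, 34.1 in the Ptbp1 knockdown, 17.5 in the Ptbp2 knockdown and 17.4 in the double knockdown (97.8%, 46.7% and 50.9% of control by exon reads). Less MBNL activity may follow: the 54-nucleotide exons of Mbnl1 (chromosome 3, 60418605 to 60418658) and Mbnl2, both known to be skipped when MBNL proteins are abundant, were more included with the Ptbp2 shRNA in each comparison, by 17.0 points or more (17.0 and 25.6 for Mbnl1, 28.3 for Mbnl2 against control). Mbnl2 was at 48.1%, 53.4%, 76.5% and 83.4% in the 4 libraries. This exon of Mbnl1 was at 67.6%, 60.3%, 84.6% and 85.9%. An effect of the Ptbp2 shRNA on Mbnl1 other than through Ptbp2 cannot be told apart from loss of Ptbp2, since a single shRNA was used. The double against the Ptbp1 knockdown gave a log2 difference of -0.94. Both libraries with the Ptbp2 shRNA also lie on the same side of the record split. A difference between its sides cannot be told apart either.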
